A study of Mus musculus with 13 samples.

How the data were processed

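RNA was extracted from the colon and the ileum of female FVB mice that carried a syngeneic mammary carcinoma expressing human HER2. It was labelled with biotin and hybridised to 1-colour Affymetrix mouse arrays, per the labels' protocols. The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA and Affymetrix Expression Console 1.4.1.46, per the submitters' processing notes. The notes do not state the role of each. RMA corrects the background, quantile-normalizes the arrays and summarizes the probes of a probe set on the log2 scale, so a difference of 1 is nominally a doubling. The values ran from 3.01 to 18.25 with array medians between 7.98 and 8.14, were not centred per gene, and were rounded by the authors to 2 decimals. Of 28846 probe sets, 437 held a value above 16, the log2 limit of a 16-bit scanner. Which step placed values there is not given in the sources used here, so log2 differences should be read as differences on the deposited scale and not as exact intensity ratios. No columns were identical, and 0 columns of the table were left unused.

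The platform annotation paired 19572 probe sets with exactly 1 gene symbol, 0 with several and 9274 with none. The last group comprised 5222 negative-control, 1324 positive-control and 94 other control probe sets and 2634 probe sets that are unnamed here. Symbols were updated through Entrez identifiers in a RefSeq table of GRCm38.p6, in which all 19572 matched and 0 symbols changed. No coordinates are given, because the build of the array annotation is not given in the sources used here. The 19572 probe sets represent 19505 genes, and 55 genes have several probe sets. For these the probe set with the highest mean over all arrays stood for the gene. No detection calls were used. The negative controls gave no usable background: their median was 8.08, as bright as the median gene, and 87.4% of the named probe sets had a mean below their 95th percentile of 12.27. Levels are therefore not called detected or absent. The ability to tell positive from negative controls, as an area under the curve, ranged from 0.772 to 0.827 per array.

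The 13 arrays form 4 groups by tissue and treatment, with 4 arrays of colon without antibiotic and 3 in each other group. All 13 arrays were fitted with a model of group means in limma 3.58.1 (R 4.3.3, lmFit and eBayes), which shares 1 estimate of the spread between groups. Each comparison was a contrast of that fit. P-values were adjusted by Benjamini-Hochberg over the 19572 probe sets, with a threshold of 0.05. Errors of log2 changes are standard errors from that fit. The labels do not say that arrays come from separate mice, so the p-values measure the spread between these samples, which could be technical. The labels also give no cage, batch or date, so cage and treatment could not be separated.

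Before the data were examined, 43 gene lists, the alternatives and the rule for naming genes were fixed. The lists cover epithelial cell types, metabolism, immune cells and pathways, stromal cells and adjoining tissues. Of 652 list entries 596 were matched to a probe set, and 4 genes stand in several lists. Lists were tested with limma's camera at a preset correlation between genes of 0.01, on 1 probe set per gene, with adjustment over the 43 lists. Camera asks whether a list's genes moved relative to all other genes. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were the alternatives. The count of list members past the threshold is given over all genes tested and adjusted over the list alone. In colon and ileum the named genes are the 12 largest rises and the 12 largest falls among genes past the threshold whose values did not overlap between the groups, filled to 6 per direction by unadjusted p. To these come up to 4 members of each list with the smallest p, and Reg3g, Reg3b, Retnlb, Angptl4, Fgf15, Slc10a2 and Nos2. For the difference between tissues, 6 genes per direction were named, and 8 for the comparison of the tissues. Predicted genes were counted and not named in the ranked part. Duox2, also fixed for naming, had no named probe set and is not analysed here.

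The steps were tested on simulated data with 200 changed genes among 19572. Each probe set had its real mean per tissue, or over all arrays for colon against ileum, and 1 real spread for all groups. Changes of 1, 2 and 3 on the log2 scale were recovered in 58.2%, 100% and 100% of cases for the colon, in 67.2%, 95.5% and 100% for the ileum, in 40.3%, 83.6% and 98.5% for the difference between tissues, and in 71.6%, 97.0% and 98.5% for colon against ileum. False calls made up 4.97%, 5.91%, 5.73% and 7.29% of the calls. The simulated genes varied independently of each other, which real genes do not. They had the same spread in every group, so the simulation could not test unequal spreads.

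The alternatives were a fit of each tissue alone (or of the no-antibiotic arrays alone), eBayes with a trend and with a robust prior, array weights, removal of the dimmest 33.3% or 50% of probe sets, quantile normalization over all arrays or within each tissue, equal array medians, all rows of the table, 1 probe set per gene, an added 1.5-fold minimum, the replicate number as a random or fixed block, and each array left out in turn. A fit with the mean of the smooth muscle list as a covariate was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.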

Results

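Expression was measured in the colon and ileum of female FVB mice bearing a transplantable mammary carcinoma that expresses human HER2, a receptor of the ErbB family. Treated mice drank water with vancomycin, a glycopeptide antibiotic that acts on Gram-positive bacteria, at 200 mg/L from 4 weeks of age. The experiment ended at 9 weeks, whether of age or of treatment is not stated, with tumours of 150 mm3. The 13 arrays comprised 4 of colon without antibiotic, 3 of colon with vancomycin, 3 of ileum without antibiotic and 3 of ileum with vancomycin. The number of arrays limits the precision of every value below. Values are RMA log2 values, and changes are differences of group means on that scale with their standard error (SE) from limma. The first principal component of the 19572 named probe sets held 66.7% of the variance and separated colon from ileum. Replicate 11 of the vancomycin ileum stood apart from the rest, with a mean correlation to its own group of 0.977, against 0.983 and 0.987 for the other vancomycin ilea. Its smooth muscle list mean was 13.21, against 11.90 and 12.28 in the other vancomycin ilea and 11.66 to 11.90 in the ilea without antibiotic. Its B cell list mean was 10.51, against 7.46 to 8.30 in the other ilea.

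Colon and ileum without antibiotic were compared first, as a reference for the tissues. Colon had higher Car1, a carbonic anhydrase of surface colonocytes, by 9.46 ± 0.27 (SE, 4 against 3 arrays), and higher Aqp8, a water channel, by 8.16 ± 0.43. Hoxb13, a homeobox gene of the posterior gut, was higher by 7.40 ± 0.38. Ileum had higher Apoa1, an apolipoprotein, with a colon minus ileum change of -10.33 ± 0.34, and higher Npc1l1, which takes up cholesterol, at -8.95 ± 0.40. The ileum was also higher in Sis, which encodes sucrase-isomaltase (-8.78 ± 0.26), in Defa34, an alpha-defensin of Paneth cells (-9.01 ± 0.50), and in Cubn, the receptor for intrinsic factor with vitamin B12 (-9.74 ± 0.43). Abcg5, a sterol exporter, stood at -8.54 ± 0.38. The other named genes were Ccn3 (8.33), Lpo (8.12), Cyp2d34 (8.04), Hao2 (7.35) and Sycn (7.35) for colon and Naaladl1 (-11.25) and Bcl2l15 (-8.66) for ileum. In limma, 4020 of 19572 probe sets passed, 2144 higher in colon and 1876 lower. Of these, 3931 had no overlap between the groups. Across all probe sets 32.2% had no overlap, where chance gives 5.71%. The 16 named genes remained past the threshold in every alternative run.

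The second comparison asked how vancomycin changed expression in the ileum. Vancomycin ilea had lower expression of epithelial genes that respond to bacteria, of MHC class I genes that present antigen, and of genes of cytotoxic lymphocytes. Ceacam10, a carcinoembryonic antigen family member, fell by 4.20 ± 0.23 (SE), from 12.55 ± 0.12 to 8.35 ± 0.40 (SD, n = 3 each). Nos2, the inducible nitric oxide synthase, fell by 3.50 ± 0.37, from 12.54 ± 0.21 to 9.04 ± 0.55. H2-Eb1, an MHC class II chain, fell by 2.93 ± 0.31, and Gzmb, granzyme B of cytotoxic lymphocytes, fell by 3.54 ± 0.42. Fgf15, the ileal hormone that restrains bile acid synthesis in the liver, fell by 3.68 ± 0.49, from 9.69 ± 1.41 to 6.01 ± 0.47.

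Of 19572 probe sets, 105 passed in limma, 10 higher and 95 lower with vancomycin. All 105 had no overlap between the 3 and 3 arrays; among all probe sets 16.9% had none, where chance gives 10%. The remaining large falls were U90926 (-4.46 ± 0.47), Igtp, an interferon-inducible GTPase (-4.10 ± 0.44), Ubd, the ubiquitin-like modifier Fat10 (-3.69 ± 0.33), Duoxa2, the maturation factor of the dual oxidase Duox2 (-3.50 ± 0.65), Gzma, granzyme A (-3.45 ± 0.54), Saa1, a serum amyloid A (-3.17 ± 0.56), and Ido1, which degrades tryptophan (-3.11 ± 0.39). The rises were smaller. Pnliprp2, a lipase related to pancreatic lipase, rose by 2.0 ± 0.36, Bche, butyrylcholinesterase, by 1.49 ± 0.29, and Akr1c19, an aldo-keto reductase, by 1.28 ± 0.22. Pcdh19 (1.12), Fam161a (1.11), Osbpl1a (1.09), Pam (0.86), Stxbp6 (0.85) and Insr, the insulin receptor (0.80), also rose. A fit of the ileum arrays alone called 20 probe sets, 2 higher and 18 lower, and array weights called 1012, 478 higher and 534 lower. The count was 56 (2 higher) without no-antibiotic replicate 1, 40 (0 higher) without no-antibiotic replicate 3, 56 (7 higher) without vancomycin replicate 13 and 172 (42 higher) without vancomycin replicate 11. Of the 36 named genes past the threshold, 19 kept their call whichever ileal array was left out, 10 in every other alternative and 9 in all of them. The fit of the ileum alone lost 24 of the 36 calls, among them Fgf15, Gzmb, H2-Eb1, Igtp, U90926 and Ido1, with adjusted p of 0.0503 to 0.296 over the 24. The main fit assumes the same spread of a gene in every group, and some of these genes varied more in the ileum. Without antibiotic, Fgf15 ran from 8.06 to 10.56 in the ileum and from 4.60 to 5.10 in the colon. U90926 ran from 8.94 to 11.47 and from 5.54 to 6.53. For such genes the standard errors given here may be too small for the ileum. The 9 named rises each lost the call without no-antibiotic replicate 1 or 3 or vancomycin replicate 13. Among the falls, Duoxa2, Elf3, Cd6, Irf8 and Prdm1 did so too without each of these 3 arrays in turn, Ccl28 without any ileal array but vancomycin replicate 13, and Gzma and Saa1 without vancomycin replicate 13.

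**Figure D1:**
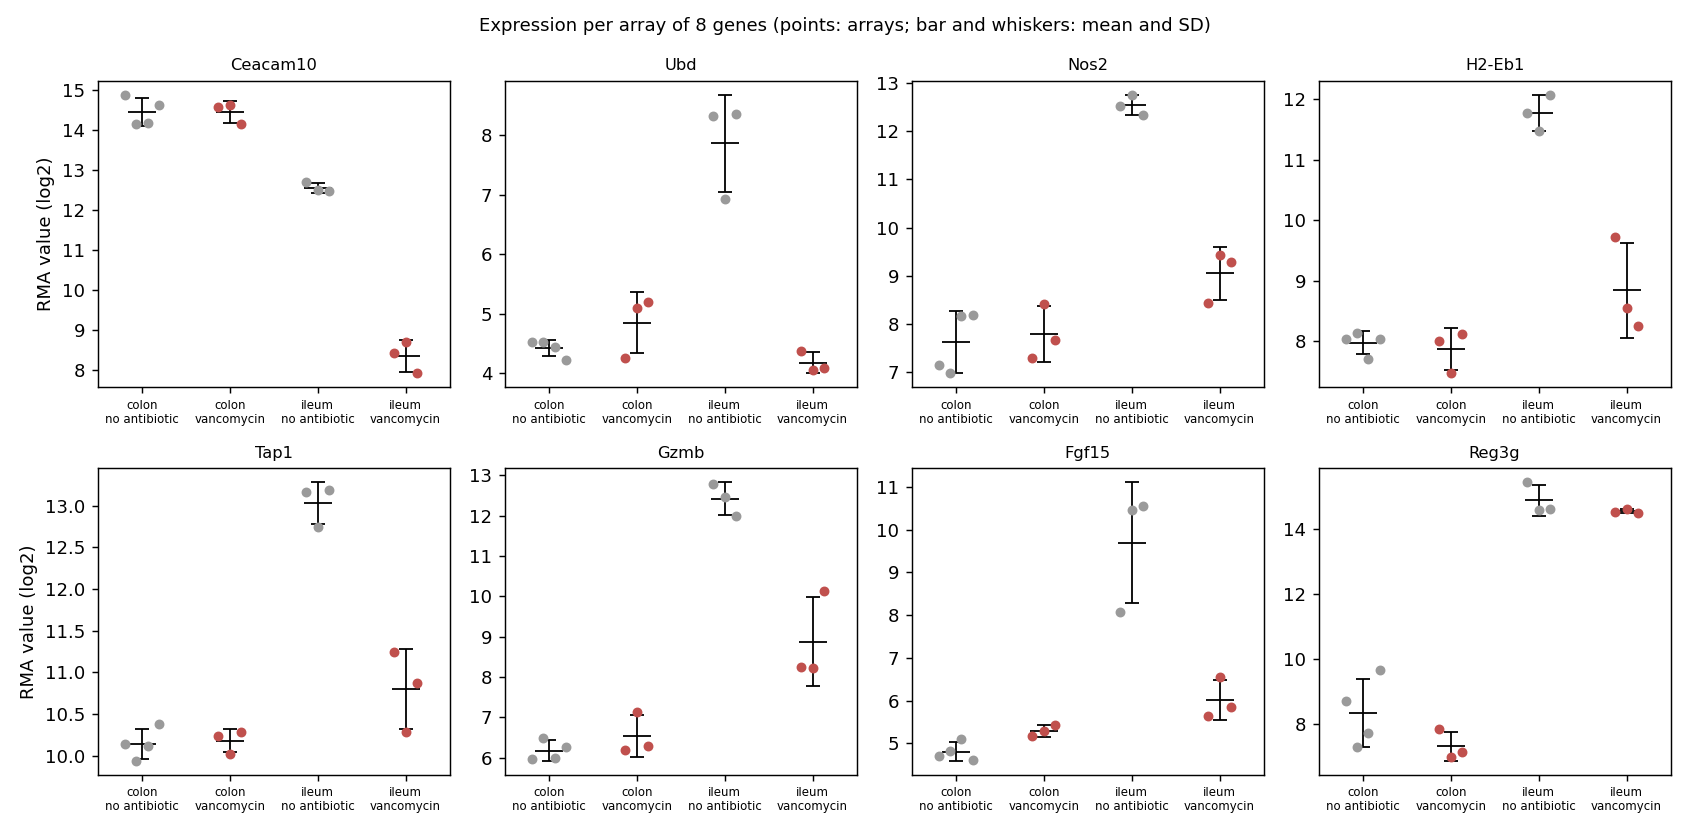
RMA log2 value (vertical axis) of 8 genes in each of the 13 arrays, by tissue and treatment; points are arrays, and the bar with whiskers is the mean and SD. Nos2 lay at 12.54 ± 0.21 in the ileum without antibiotic and at 9.04 ± 0.55 with vancomycin, while Reg3g was 14.88 ± 0.48 and 14.55 ± 0.06.

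All 10 measured genes of MHC class I presentation had lower means with vancomycin (median -0.77). Tap1, which carries peptides into the endoplasmic reticulum (-2.23 ± 0.22), and the immunoproteasome subunits Psmb9 (-1.97 ± 0.23) and Psmb8 (-1.75 ± 0.26) fell, 3 over all genes and 9 adjusted over the list alone. Camera gave an adjusted p of 2.95e-17, and 0.000655 with an estimated correlation. Of the 10 genes of MHC class II presentation, 4 fell over all genes and 7 adjusted over the list alone (median -1.58). Beside H2-Eb1, these were H2-Ab1 (-2.11 ± 0.25), H2-DMa (-2.73 ± 0.33) and H2-Aa (-1.67 ± 0.25). Camera gave an adjusted p of 3.74e-11, with an adjusted p of 0.143 with an estimated correlation. Vancomycin replicate 11 had a class II list mean of 11.2, against 10.03 and 9.79 in the other vancomycin ilea and 11.41 to 11.73 without antibiotic. Among 15 epithelial genes that respond to bacteria, Ubd, Nos2, Ido1, Saa1 and Duoxa2 fell over all genes and 7 adjusted over the list alone (median -0.89). The list's adjusted p was 3.18e-11, and 0.0251 with an estimated correlation; its median was -0.59 without no-antibiotic replicate 1. Reg3g and Reg3b, secreted antibacterial lectins, differed by -0.33 ± 0.47 (adjusted p = 0.85) and 0.01 ± 0.44 (adjusted p = 0.996) in limma, and by -0.0550 and 0.37 without no-antibiotic replicate 1. Retnlb (-0.93, adjusted p = 0.656) and Angptl4 (0.81, adjusted p = 0.533), also fixed for naming, did not pass in limma. Angptl4 passed without vancomycin replicate 11 (1.42, adjusted p = 0.0326) and was at 0.42 without vancomycin replicate 13.

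Of 16 genes of cytotoxic and intraepithelial lymphocytes, 8 fell over all genes; adjusted over the list alone, 8 fell and 1 rose (median -0.64, and -1.74 without the dimmest 33.3% of probe sets). Cd7, a surface receptor of T and NK cells, fell by 2.56 ± 0.26, Nkg7, a granule protein, by 1.83 ± 0.19 and Cd244a, an NK cell receptor, by 1.65 ± 0.18. The list's adjusted p was 6.07e-11, and 0.0251 with an estimated correlation. The T cell list fell (median -0.43, adjusted p = 0.000208; adjusted p = 0.519 with an estimated correlation), with 1 of 14 genes down over all genes and 5 adjusted over the list alone. That gene was Cd6 (-1.19 ± 0.23), while the receptor genes Cd3g (-1.79 ± 0.38), Cd8a (-1.35 ± 0.30) and Cd3e (-0.89 ± 0.25) did not pass over all genes. The plasma cell list fell (median -0.49, adjusted p = 3.66e-05; adjusted p = 0.12 with an estimated correlation). Of its 10 genes, Prdm1, the regulator of plasma cell fate, fell over all genes (-1.59 ± 0.31) and 4 adjusted over the list alone. Jchain, the joining chain of secreted IgA, stood at -1.83 ± 0.46. In the interferon-stimulated list (median -0.40, adjusted p = 7.64e-05; adjusted p = 0.453 with an estimated correlation), Zbp1, a nucleic acid sensor, fell by 2.89 ± 0.30, and 4 of 18 genes fell adjusted over the list alone. The T cell median was -0.73 and the plasma cell median -0.78 without vancomycin replicate 11, the T cell median -0.28 and the interferon-stimulated median -0.23 without vancomycin replicate 13, and the last -0.69 without vancomycin replicate 14. Ifit1 (-1.68 ± 0.38), Rsad2 (-1.13 ± 0.34) and Isg15 (-1.14 ± 0.38) did not pass over all genes. With 1 array left out, Cd3g (-2.23), Cd3e (-1.17) and Jchain (-2.31) passed without vancomycin replicate 11, Cd8a (-1.76) without no-antibiotic replicate 2 and Ifit1 (-2.06) without vancomycin replicate 14.

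The bile acid list fell (median -0.11, adjusted p = 0.0192; adjusted p = 0.433 with an estimated correlation), with Fgf15 down over all genes and 4 of 15 genes down adjusted over the list alone. Nr0b2, the repressor SHP (-1.52 ± 0.42), Abcc3, a bile salt exporter (-0.77 ± 0.20), and Osgin1 (-0.53 ± 0.17) did not pass over all genes, and Slc10a2, the ileal bile acid transporter, was at -0.11 ± 0.33. The proliferation list fell (median -0.46, adjusted p = 3.44e-07; adjusted p = 0.519 with an estimated correlation), with 0 of its 18 genes past the threshold alone and all 18 negative. The lists of the unfolded protein response (median -0.24; adjusted p = 0.453 with an estimated correlation), epithelium (-0.12; 0.6) and xenobiotic metabolism (-0.10; 0.6) fell with adjusted p of 0.00914, 0.031 and 0.0362. Without vancomycin replicate 11 4 lists lost the call: the bile acid median was 0 (adjusted p = 0.326), the unfolded protein response median -0.16 (0.0981), the epithelium median turned to 0.00833 (0.826) and the xenobiotic median was -0.0533 (0.827). The xenobiotic list also lost it without no-antibiotic replicate 2 (median -0.0183, adjusted p = 0.123) and the epithelium list without no-antibiotic replicate 3 (-0.10, 0.0510). Without vancomycin replicate 14 the medians were -0.23 for proliferation, -0.30 for bile acid, -0.28 for xenobiotic and -0.25 for epithelium, and without no-antibiotic replicate 3 they were -0.05 for bile acid and -0.14 for the unfolded protein response, with the call kept. The call was also kept without vancomycin replicate 13, at -0.23 for bile acid and -0.25 for xenobiotic, and for xenobiotic at -0.16 without no-antibiotic replicate 1 and -0.20 without no-antibiotic replicate 3. Nr0b2 passed without no-antibiotic replicate 1 (-2.25). Elf3, an epithelial transcription factor, fell by 1.08 ± 0.21, and Hnf4a stood at -0.69 ± 0.21 (-0.42 without vancomycin replicate 11). Creld2 (-0.87 ± 0.21) and Sdf2l1 (-0.68 ± 0.19) of the unfolded protein response did not pass. Irf8, which directs dendritic cell development, fell by 1.41 ± 0.24 within a list that did not pass, and Ccl28, an epithelial chemokine, by 1.11 ± 0.21. Ccl3 (-0.70), Cxcl9 (-1.43, and -0.81 without no-antibiotic replicate 1) and Ccl4 (-0.52) did not pass over all genes.

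The lists of smooth muscle (median 0.78, adjusted p = 2.59e-05; adjusted p = 0.519 with an estimated correlation), B cells (0.66, adjusted p = 0.0192; 0.683), adipocytes of adjoining fat (0.37, adjusted p = 0.0333; 0.6), endothelial cells (0.35, adjusted p = 0.00766; 0.58), fibroblasts and matrix (0.31, adjusted p = 0.0113; 0.519) and enteric neurons and glia (0.29, adjusted p = 0.0362; 0.6) rose, with 0 genes of any of these past the threshold. Without vancomycin replicate 11, in which the smooth muscle mean was 13.21, none of these 6 lists passed as higher. The B cell median turned to -0.21 without it, and the others were 0.35 for smooth muscle, 0.22 for adipocytes, 0.20 for fibroblasts, 0.12 for endothelial cells and 0.0275 for neurons and glia; with array weights the adipocyte median was -0.0431. Without vancomycin replicate 14 the medians were 1.39 for B cells, 0.57 for endothelial cells and 0.52 for neurons and glia, and adipocytes lost the call (0.23); neurons and glia lost it without no-antibiotic replicate 1 (0.19), and the adipocyte median was 0.80 without vancomycin replicate 13. Without no-antibiotic replicate 2 B cells (0.47), adipocytes (0.35) and neurons and glia (0.34) lost the call. In all, 18 of 43 lists passed, 6 higher and 12 lower, and 10 passed without replicate 11. Of the 10 ways to split the 6 ileum arrays 3 gave at least 18, and ways other than the real one had a median of 14. A camera call at the preset correlation is therefore by itself weak evidence of an effect of vancomycin. The calls of 3 lists held with an estimated correlation: MHC class I, cytotoxic lymphocytes and epithelial genes that respond to bacteria. By fry 5 lists passed, these 3 and the MHC class II and plasma cell lists. The 25 other lists did not pass; they include Paneth cells, goblet cells, enterocytes, type 17 immunity, tuft cells, stem cells and the circadian clock.

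**Figure D2:**
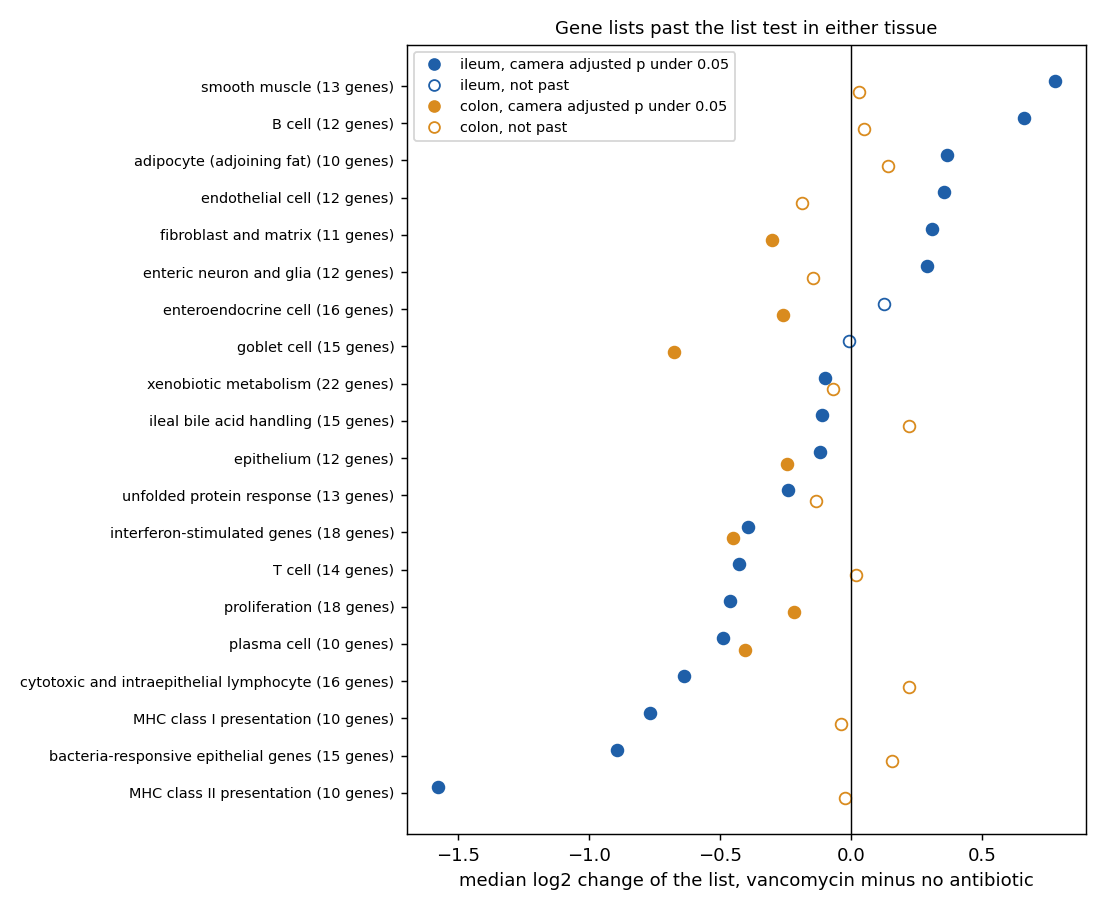
Median log2 change of each gene list with vancomycin (horizontal axis), in ileum (blue) and colon (orange), for the lists that passed camera in either tissue; filled points passed, open points did not. MHC class II presentation was at -1.58 in the ileum, and the goblet cell list at -0.68 in the colon.

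The third comparison asked the same of the colon. Genes of goblet cells, which make mucus, and of enteroendocrine cells were lower in the vancomycin colon as lists in camera, with an adjusted p of 0.767 with an estimated correlation for each. Ly6g6c, a member of the Ly6 family, fell by 1.70 ± 0.21, from 9.43 ± 0.43 (SD, n = 4) to 7.73 ± 0.16 (n = 3). Fam162b fell by 0.95 ± 0.12, from 6.36 ± 0.14 to 5.41 ± 0.09. All 15 goblet cell genes had lower means with vancomycin (median -0.68).

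These were the only 2 of 19572 probe sets past the threshold in limma (adjusted p = 0.0212 for each), 0 higher and 2 lower, where 3107 had an unadjusted p under 0.05 and 979 are due by chance. In the ileum 1977 had an unadjusted p under 0.05. Among all probe sets 12.3% had no overlap between the colon groups, where chance gives 5.71%. The few calls therefore do not show that fewer genes moved in the colon than in the ileum. A fit of the colon arrays alone called 0, and array weights 38. The next genes in order of p, none past the threshold, were lower Srm, spermidine synthase (-1.03 ± 0.15), Nectin1 (-0.88 ± 0.15), Tph1, which starts serotonin synthesis in enterochromaffin cells (-1.32 ± 0.22), and Ffar4, a receptor for long-chain fatty acids (-2.32 ± 0.40). On the higher side they were Luc7l2 (0.77 ± 0.12), Zfp867 (0.80 ± 0.14), Cflar, an inhibitor of caspase-8 (0.98 ± 0.18), Ankrd44 (1.01 ± 0.19), Zfp280c (0.95 ± 0.18) and Pus10 (0.72 ± 0.13). All 10 passed without no-antibiotic replicate 3, and all but Zfp280c and Pus10 without vancomycin replicate 11. The count was 217 without no-antibiotic replicate 3, 109 without vancomycin replicate 11, 5 without no-antibiotic replicate 5, 1 without vancomycin replicate 14 and 0 without no-antibiotic replicate 2; Ly6g6c and Fam162b each lost the call without no-antibiotic replicate 2, vancomycin replicate 13 or vancomycin replicate 14.

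Of the 43 lists, 7 passed camera in the colon, all lower, and 0 passed with an estimated correlation or by fry. The goblet cell list gave an adjusted p of 1.83e-10, and an adjusted p of 0.767 with an estimated correlation. Adjusted over the list alone, 11 of its 15 genes fell, among them Zg16, a mucus lectin (-1.33 ± 0.27), Atoh1, the secretory lineage factor (-1.08 ± 0.25, and -0.69 without vancomycin replicate 14), Galnt12, which starts mucin glycosylation (-1.48 ± 0.35), and Ccl6 (-0.83 ± 0.18); 0 passed over all genes. The list mean was lower in every vancomycin array than in every array without antibiotic, and an exact permutation test gave p = 0.0286, the smallest that 4 against 3 arrays allow (adjusted p = 0.307 over the lists). That test gave the same p for the plasma cell and epithelium lists, also lower, and for the cytotoxic lymphocyte list, which was higher by 0.18. The enteroendocrine list fell (median -0.26, adjusted p = 0.0116; adjusted p = 0.767 with an estimated correlation), with Tph1 and Pyy, peptide YY (-1.14 ± 0.27), down adjusted over the list alone. The plasma cell list fell (median -0.41, adjusted p = 0.0116; adjusted p = 0.767 with an estimated correlation), with 2 genes down adjusted over the list alone; Jchain was at -1.32 ± 0.43 (-0.72 without vancomycin replicate 14) and Xbp1, a factor of secretory cells, at -0.52 ± 0.16. The interferon-stimulated list fell (median -0.45, adjusted p = 0.00212; adjusted p = 0.926 with an estimated correlation), led by Irf7 (-2.15 ± 0.57). Epithelium (median -0.25, adjusted p = 0.00693), proliferation (-0.22, adjusted p = 0.00212) and fibroblasts and matrix (-0.30, adjusted p = 0.0214) also fell, each with an adjusted p of 0.926 with an estimated correlation. Krt18 (-0.53 ± 0.16), Elf3 (-0.61 ± 0.19), Pi16 (-0.63 ± 0.14), Mfap5 (-0.99 ± 0.23) and Fbln1 (-1.05 ± 0.29) belong to these lists and did not pass over all genes. With 1 array left out, Zg16 (-1.47), Pyy (-1.35), Pi16 (-0.73) and Mfap5 (-1.16) passed over all genes without no-antibiotic replicate 3, and Galnt12 (-1.96), Ccl6 (-1.04) and Fbln1 (-1.51) without vancomycin replicate 11. Vancomycin replicate 14 had the lowest goblet mean (13.87, against 14.49 and 14.72) and the lowest separation of control probe sets (0.772). The fibroblast list lost the call without no-antibiotic replicate 3 (median -0.11, adjusted p = 0.0928), no-antibiotic replicate 5 (-0.19, 0.0724) or vancomycin replicate 13 (-0.16, 0.0867). The proliferation list (-0.11, 0.145) and the interferon-stimulated list (-0.28, 0.124) lost it without vancomycin replicate 11, the enteroendocrine list without vancomycin replicate 13 (-0.13, 0.0517), and the plasma cell list without no-antibiotic replicate 5 at a median of -0.42 (0.0564). The proliferation median was -0.36 without no-antibiotic replicate 1 and -0.51 without vancomycin replicate 13, and the enteroendocrine median -0.50 without vancomycin replicate 11. Without no-antibiotic replicate 1, 11 lists passed. Of the 35 ways to split the 7 colon arrays 16 gave at least 7 lists, and ways other than the real one had a median of 6. The list calls are by themselves weak evidence here too.

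The 36 other colon lists did not pass. Some members passed adjusted over their list alone. The macrophage genes Mrc1, the mannose receptor (-1.01 ± 0.20), Cx3cr1 (-0.78 ± 0.20) and Fcgr3 (-0.64 ± 0.21) were lower, as were Cldn4 (-1.29 ± 0.32) and Cldn23 (-0.69 ± 0.21) of the tight junction, Pla2g2a (-1.18 ± 0.32) and Ffar2, a receptor for short-chain fatty acids (-1.15 ± 0.30). Acss2, which activates acetate (0.73 ± 0.22), and Mcpt1, a mast cell protease of the mucosa (1.11 ± 0.25), were higher. Of the clock genes, Nfil3 was lower (-0.95 ± 0.23), and Nr1d2 (0.75 ± 0.21) and Per3 (0.77 ± 0.24) were higher. Reg3g (-1.03 ± 0.44), Reg3b (-0.44 ± 0.41), Retnlb (-1.88 ± 0.61), Angptl4 (0.03 ± 0.39), Fgf15 (0.49 ± 0.45), Slc10a2 (-0.97 ± 0.31) and Nos2 (0.17 ± 0.35) did not pass in limma. Over all genes, Mrc1 (-1.12) and Acss2 (0.93) passed without no-antibiotic replicate 3, and Nfil3 (-1.23), Ffar2 (-1.48) and Retnlb (-2.83) without vancomycin replicate 11. Without no-antibiotic replicate 5, Reg3g was at -0.59 and Reg3b at -0.10, and Reg3b was at -0.77 without no-antibiotic replicate 2 and at -0.0825 without vancomycin replicate 13.

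**Figure D3:**
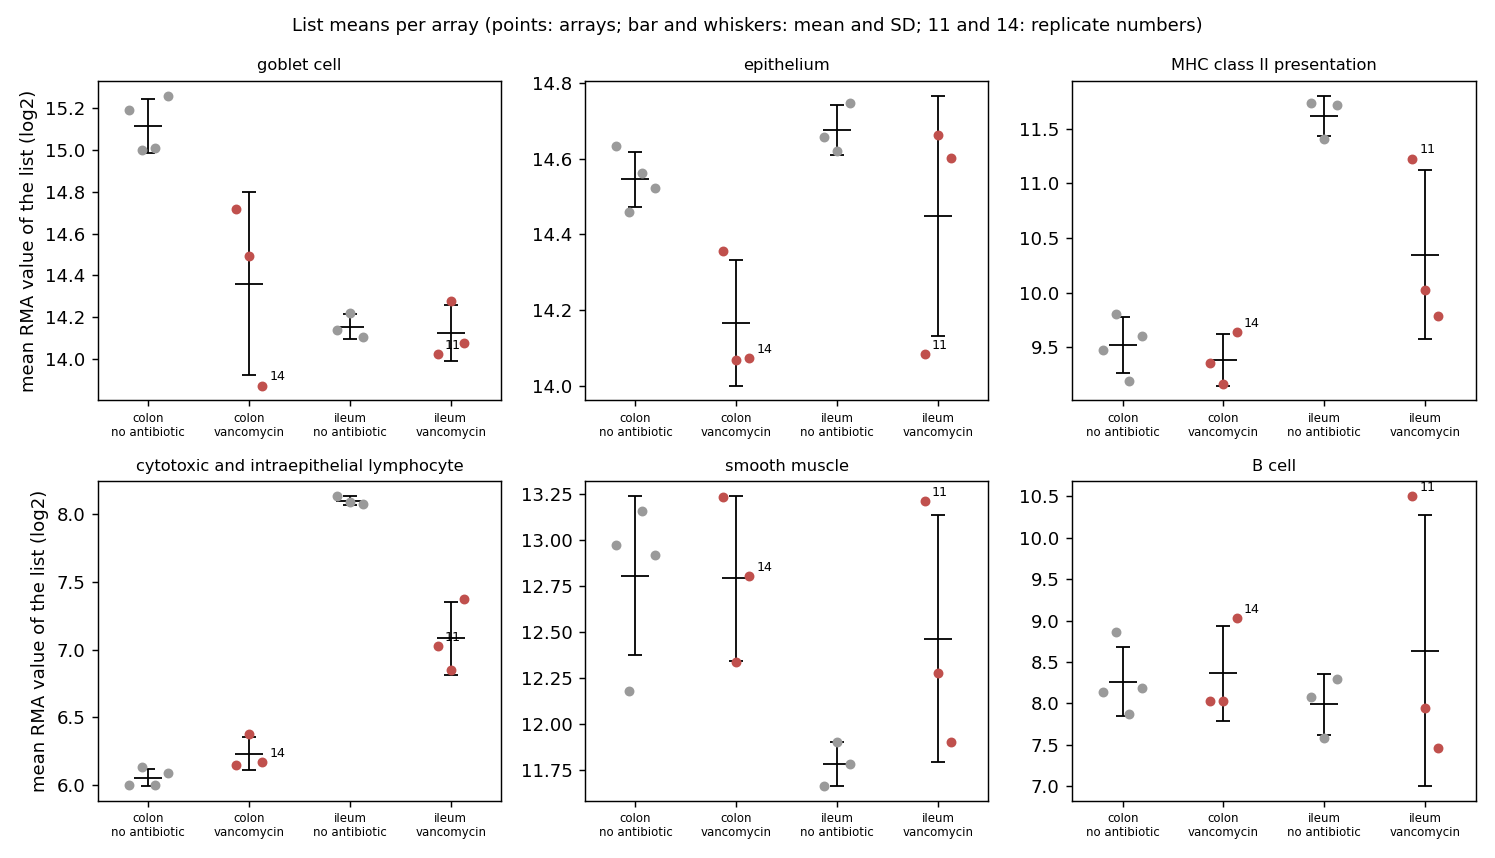
Mean RMA log2 value of 6 gene lists (vertical axis) in each of the 13 arrays, by tissue and treatment; points are arrays, bars and whiskers the mean and SD, and 11 and 14 mark the vancomycin ileum and colon arrays named in the text. Replicate 11 of the vancomycin ileum had a B cell mean of 10.51 and a smooth muscle mean of 13.21, and replicate 14 of the vancomycin colon a goblet mean of 13.87.

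The last comparison tested whether the vancomycin effect differed between the tissues, as the ileum change minus the colon change. The falls of Ceacam10, Ubd, Nos2, U90926, Gzmb and Fgf15 in the ileum had no counterpart of their size in the colon. In the colon without antibiotic Ubd lay at 4.23 to 4.52 and Fgf15 at 4.60 to 5.10. U90926 lay at 5.54 to 6.53 and Gzmb at 5.96 to 6.49. The lowest value of the table was 3.01, so these genes had no room for a fall of the ileal size. For them the difference cannot tell a tissue-specific response from a low starting level. Nos2 lay at 6.97 to 8.18, with little room, and Ceacam10 at 14.14 to 14.87. The differences were -4.19 ± 0.32 for Ceacam10, -4.11 ± 0.45 for Ubd, -3.67 ± 0.51 for Nos2, -4.59 ± 0.64 for U90926, -3.91 ± 0.58 for Gzmb and -4.17 ± 0.66 for Fgf15. The difference was 2.10 ± 0.33 for Tph1 and -2.17 ± 0.37 for Mcpt1. For these 2 genes only the difference passed: the changes were -1.32 in colon and 0.79 in ileum for Tph1 (adjusted p of 0.0968 and 0.233 in limma), and 1.11 and -1.06 for Mcpt1 (0.102 and 0.129).

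In limma 37 of 19572 probe sets passed, 6 with a higher and 31 with a lower ileal change; array weights gave 191, 72 higher and 119 lower. The higher ones included Pnliprp2 (2.74 ± 0.50), Cd248, the endosialin of stromal cells (2.25 ± 0.40), Pde8a, a cyclic AMP phosphodiesterase (1.86 ± 0.32), Ly6g6c (1.71 ± 0.31) and Tagln2, an actin-binding protein (1.17 ± 0.20). Of 43 lists 13 passed, 7 higher and 6 lower in the ileum relative to the colon. Of 100 drawn splits 48 gave at least 13, and splits other than the real one had a median of 12. Cytotoxic lymphocytes (median -0.97, and -1.94 without the dimmest 33.3%; adjusted p = 7.27e-13; adjusted p = 0.0138 with an estimated correlation) and MHC class I presentation (-0.75, adjusted p = 1.53e-12; adjusted p = 0.00253 with an estimated correlation) kept the call with an estimated correlation. MHC class II presentation (median -1.65, adjusted p = 6.96e-08; adjusted p = 0.203 with an estimated correlation) and the goblet cell list (0.66, adjusted p = 2.44e-08; adjusted p = 0.203 with an estimated correlation) did not. Without antibiotic the cytotoxic list mean was 6.06 in the colon and 8.10 in the ileum. The vancomycin ileum, at 7.08, was still above that colon level. For this list too the difference cannot tell a tissue-specific response from a low starting level. The MHC class I means without antibiotic were 12.07 in colon and 13.74 in ileum, and the class II means 9.52 and 11.62. The calls of Ceacam10, Ubd, Nos2 and U90926 held in every alternative, and the other 9 named genes lost theirs in at least 1. Tph1 lost it without colon no-antibiotic replicate 1, colon vancomycin replicate 13 or 14, ileum no-antibiotic replicate 3 or ileum vancomycin replicate 13 (adjusted p up to 0.0721), and Mcpt1 without colon no-antibiotic replicate 1, 3 or 5, colon vancomycin replicate 13, any ileum no-antibiotic replicate or ileum vancomycin replicate 14 (up to 0.0995). Fgf15 lost it without colon no-antibiotic replicate 1 or 5, colon vancomycin replicate 13 or 14, ileum no-antibiotic replicate 3 or ileum vancomycin replicate 14, and Gzmb without colon vancomycin replicate 13 or ileum no-antibiotic replicate 1. With 0 higher, the count was 12 without colon vancomycin replicate 13 or ileum no-antibiotic replicate 3, and 17 without colon no-antibiotic replicate 1 or colon vancomycin replicate 14. It was 18 (1 higher) without ileum no-antibiotic replicate 1, 21 (3 higher) without colon no-antibiotic replicate 5 and 23 (1 higher) without colon no-antibiotic replicate 2. It was 84 without ileum vancomycin replicate 11 and 55 without colon vancomycin replicate 11, with 20 higher in each.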

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

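The counts of other splits and the matched random lists were chosen before their results were seen; the tests without replicate 11 or 14, with the smooth muscle list as a covariate, and of list means per array were chosen only after.

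The vancomycin effect differed between the tissues in 37 probe sets by limma's test of the difference. The difference, ileum change minus colon change, was -4.59 for U90926, -4.19 for Ceacam10, -4.17 for Fgf15, -4.11 for Ubd, -3.91 for Gzmb and -3.67 for Nos2. It was 2.74 for Pnliprp2, 2.25 for Cd248, 2.10 for Tph1, 1.86 for Pde8a, 1.71 for Ly6g6c and 1.17 for Tagln2. Ubd, Fgf15, U90926 and Gzmb started too low in the colon to fall as far there as in the ileum. For gene lists, the median difference was -1.65 for MHC class II presentation, -1.02 for epithelial genes that respond to bacteria, -0.97 for cytotoxic and intraepithelial lymphocytes, -0.75 for MHC class I presentation, -0.30 for T cells and -0.20 for ileal bile acid handling. The median was 0.70 for fibroblasts and matrix, 0.69 for smooth muscle, 0.66 for goblet cells, 0.53 for endothelial cells, 0.51 for enteroendocrine cells, 0.32 for enteric neurons and glia and 0.17 for Paneth cells. With an estimated correlation MHC class I (adjusted p = 0.00253) and cytotoxic lymphocytes (0.0138) kept the call, and the other 11 lists lost it, with adjusted p of 0.127 to 0.863. The cytotoxic list also started low in the colon, at a mean of 6.06 against 8.10 in the ileum without antibiotic. Its difference therefore cannot tell a tissue-specific response from a low starting level. The Paneth cell median turned to -0.17 without ileum vancomycin replicate 11 and to -0.0325 without ileum no-antibiotic replicate 1, and the list lost its call in each case. Without ileum vancomycin replicate 11 the median was 0.0333 for neurons and glia, 0.23 for endothelial cells, 0.32 for smooth muscle, 0.29 for fibroblasts, -0.12 for bile acid handling and -0.72 for T cells, and all of these but fibroblasts and T cells lost the call. T cells lost it without ileum vancomycin replicate 14 (-0.15), neurons and glia without colon vancomycin replicate 13 (0.24), and Paneth cells also without colon no-antibiotic replicate 3 (0.12), colon vancomycin replicate 11 (0.12) or ileum no-antibiotic replicate 3 (0.22). With the call kept, the enteroendocrine median was 0.32 without colon no-antibiotic replicate 1, and the bile acid median -0.36 without colon no-antibiotic replicate 5, -0.45 without colon vancomycin replicate 11 and -0.31 without ileum vancomycin replicate 13. The T cell median was -0.48, -0.47 and -0.19 without colon vancomycin replicates 11, 13 and 14, -0.17 without ileum no-antibiotic replicate 1 and -0.19 without ileum vancomycin replicate 13. The Paneth median was 0.29 and 0.0750 without colon no-antibiotic replicates 1 and 5, 0.42 without ileum no-antibiotic replicate 2 and 0.48 without ileum vancomycin replicate 14. Of 100 drawn splits, 5 gave at least 37 probe sets, the highest other being 65, so chance could not be excluded by this count. All 5 kept the vancomycin ilea together and the ilea without antibiotic together, with their labels swapped in the split that gave 65. In all, 14 of the 100 splits kept the ilea so, and the others gave at most 3. Those 14 splits carry the ileal change, so this count could not test the difference by itself. For the lists, 48 of 100 splits gave at least 13, and the highest other gave 24, so chance could not be excluded.

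The first pattern is the lower expression of MHC, bacteria-responsive and cytotoxic genes in the vancomycin ileum, over 51 members with a median change of -0.93. An effect of replicate 11 alone was argued against, since the median without it was -0.84. More muscle wall with less mucosa was argued against, since the epithelium list had a median of -0.12. Vancomycin replicates 13 and 14 had smooth muscle means of 12.28 and 11.90, against 11.66 to 11.90 without antibiotic. Their means over the members were 9.42 and 9.58, against 10.59 to 10.97. The median with the smooth muscle list mean as a covariate was -0.92. That covariate had 1 slope for ileum and colon together, so this fit alone could not decide. Fewer T cells remain open for the cytotoxic genes: their mean relative to the T cell list differed by -0.56, with an exact permutation p of 0.2, 2-sided, where 3 against 3 arrays cannot go below 0.1. A response of the ileum to vancomycin may underlie the rest, as a hypothesis, and cage stays confounded with treatment.

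The second pattern is the higher smooth muscle, B cell, adipocyte, endothelial, fibroblast and neuronal lists in the vancomycin ileum, over 70 members with a median of 0.41. Replicate 11 could account for most of it, since the median without it was 0.12. A rise shared by the vancomycin ilea was argued against for B cells and for neurons and glia, where 1 of 3 vancomycin arrays had a list mean above every array without antibiotic. It remains open for smooth muscle, endothelial cells and adipocytes, at 2 of 3 each, and for fibroblasts and matrix, at 3 of 3. More muscle wall or lymphoid tissue in the piece taken for replicate 11 is a candidate explanation.

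The last pattern is the lower goblet cell list in the vancomycin colon, with a median of -0.68 over 15 genes. A lower share of epithelium remains open: the goblet mean relative to the epithelium mean fell by 0.37 (exact permutation p = 0.0286, 2-sided, the smallest possible), but by 0.18 without replicate 14 (exact p = 0.2, where 4 against 2 arrays cannot go below 0.0667). A shift of bright probe sets was argued against, since 0 of 10000 random lists matched on mean expression had a median as low. The random lists centred on -0.0867. They were drawn gene by gene, while the goblet genes varied together (estimated correlation 0.426), so their count may overstate the evidence. Replicate 14 as the whole cause was argued against, since the median without it was -0.55. An effect of vancomycin on goblet cells may be involved, as a hypothesis, but 16 of the 35 splits of the colon arrays gave at least 7 lists, the highest other 14, so chance could not be excluded for the list count.

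Among the colon arrays, 4 of 35 splits gave at least 2 probe sets, so chance could not be excluded. The highest other gave 252: it set no-antibiotic replicates 1, 2 and 5 against no-antibiotic replicate 3 and the 3 vancomycin arrays, which is the real split with 1 array moved, and the real comparison without no-antibiotic replicate 3 gave 217. Such a count points to a structure of the samples, here 1 that overlaps with treatment, and whether it is separate from treatment was not tested. The 6 ileum arrays make 10 splits, too few for a share under 0.05; the real split gave 105 probe sets, the highest other 2, and 1 of 10 gave as many. For ileum lists the real split gave 18 and the highest other 22, with 3 of 10 as large. For colon against ileum, 1 of 35 splits gave 4020 probe sets, the real one, and the highest other gave 750. That share is the smallest these splits allow and lies under 0.05, so chance was argued against.

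In the colon without antibiotic, 4 of 124 values tested for a sample far from the others stood apart, where chance gives 6.2. Replicate 1 had a fatty acid oxidation list mean of 10.4, an immediate early and heat shock list mean of 10.01 and a pancreatic acinar list mean of 9.08, the last against 7.01 to 7.25 in the others. Replicate 5 had a short-chain fatty acid list mean of 11.3.

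The 2634 probe sets without a gene name entered no main comparison, only the alternative over all rows of the table. Among them 13 passed for the ileum (3 higher, 10 lower), 4 for the difference between tissues and 316 for colon against ileum. For the colon 0 passed in limma, where 456 had an unadjusted p under 0.05.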

How the results depend on the processing

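The smooth muscle covariate was chosen only after the data had been seen; the other alternatives were planned. Causes were not tested unless stated. The 16 genes named for colon against ileum kept their call in every alternative, and its count was 2050 with the covariate and 2910 to 3847 with 1 array left out. In the ileum the 105 probe sets became 20 in a fit of the ileum alone, which has fewer arrays to estimate the spread, and 1012 with array weights, which ran from 0.302 for vancomycin replicate 11 to 3.79 for vancomycin replicate 13; with 1 array left out they were 40 (no-antibiotic replicate 3) to 172 (vancomycin replicate 11). In the colon the 2 became 0 in the colon alone, 38 with array weights, 1 without the dimmest 33.3% and 1 without the dimmest 50%, 0 with equal medians and 6 with the covariate; with 1 array left out they were 0 (no-antibiotic replicate 2) to 217 (no-antibiotic replicate 3). The 37 of the difference became 191 with array weights and 18 over all probe sets of the table. There control and unnamed probe sets enter both the estimate of the spread and the adjustment. With 1 array left out they were 12 (colon vancomycin replicate 13) to 84 (ileum vancomycin replicate 11). For lists, the 7 of the colon became 0 with an estimated correlation, 0 by fry and 3 without the dimmest 33.3%, and 5 to 11 with 1 array left out. The 18 of the ileum became 3 with an estimated correlation, 5 by fry, 11 with array weights and 11 with the covariate, and 10 to 23 with 1 array left out. The 13 of the difference became 2 with an estimated correlation and 3 by fry, and 10 to 16 with 1 array left out.

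Arrays of colon and ileum share replicate numbers, and nothing in the labels pairs them. The deviations of same-numbered arrays from their group means correlated at 0.0754, 0.0302 and -0.0162 for numbers 1, 2 and 3 and at 0.236, 0.176 and 0.107 for 11, 13 and 14. Colon arrays 1, 11, 13 and 14 correlated best with the ileum array of their own number, and 2 and 3 did not, so the arrays are treated as sharing only a number. With the number as a random block (consensus correlation 0.0975) the counts were 2 for colon, 104 for ileum, 43 for the difference and 4389 for colon against ileum, and as a fixed block 23 for the difference and 3669 for colon against ileum; a fixed block could not be fitted for the effect within a tissue.

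Directions that reversed were mostly those of changes near 0. Angptl4 in colon was -0.0143 with array weights, -0.0180 with quantile normalization over all arrays, -0.0170 within each tissue, -0.21 without no-antibiotic replicate 5 and -0.05 without vancomycin replicate 14; it ranged up to 0.16. Nos2 in colon was -0.05 without no-antibiotic replicate 2 and -0.15 without vancomycin replicate 13, and up to 0.42. Slc10a2 in ileum was 0.15 with array weights, 0.48 with the covariate and 0.22 without replicate 11, and as low as -0.30. Reg3b in ileum was -0.0133 with equal medians, -0.0232 with the random block, -0.32 with the covariate, -0.20 and -0.14 without no-antibiotic replicates 2 and 3 and -0.06 without vancomycin replicate 13, and up to 0.37. For lists, a direction is that of the test. It reversed for adipocytes in the ileum with array weights (-0.0431), for neurons and glia with the covariate (-0.0131), for B cells without replicate 11 (-0.21, and up to 1.39 without replicate 14) and for neurons and glia without replicate 11 (median 0.0275, and up to 0.52 without replicate 14). The smooth muscle list in the difference was 0.0337 with the covariate, which is that list's own mean. Medians turned while the test kept its direction and lost its call for epithelium in the ileum without replicate 11 (0.00833) and for Paneth cells in the difference with array weights (-0.11), with the covariate (-0.25), without ileum no-antibiotic replicate 1 (-0.0325) and without ileum vancomycin replicate 11 (-0.17). Other lists lost the call at medians moved by over 1.5 times. These were bile acid in the ileum (-0.0333) and enteroendocrine cells in the colon (-0.41) without the dimmest 33.3%, and epithelium in colon (-0.14) and ileum (-0.0497) with quantile normalization over all arrays. With array weights they were fibroblasts in the colon (-0.18), bile acid (-0.0553), epithelium (-0.0450), B cells (0.11), neurons and glia (0.0807), fibroblasts (0.13) and endothelial cells (0.22) in the ileum, and bile acid (-0.0765) and neurons and glia (0.20) in the difference. With the covariate they were smooth muscle (0.0178), B cells (0.10), fibroblasts (0.0866), endothelial cells (0.0655), adipocytes (0.20), the unfolded protein response (-0.12) and epithelium (-0.00416) in the ileum, and bile acid (-0.12), neurons and glia (0.0774) and endothelial cells (0.23) in the difference. In 13 cases a median moved as far, and its direction and call were kept. Of the other values for named genes, 2456 kept their direction and side of the threshold, 240 lost the call and 75 gained it; for lists 454 kept the direction of the test and the side of the threshold and 133 lost the call. Control probe sets gave no usable background, so what signal over background limits cannot be given.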

Other observations

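The tests of the 2 gene families and of the clock genes were chosen only after the values had been seen; the correlation across all genes was planned.

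In the vancomycin ileum, Igtp (-4.10 ± 0.44, SE), Tgtp2 (-2.80 ± 0.56) and Irgm2 (-2.21 ± 0.27) passed over all genes; they are interferon-inducible GTPases, which act on vacuoles that hold intracellular microbes. The family was chosen because such members stood among the largest falls, so a test that includes them would be void. The 8 of 11 measured members that did not pass had a median of -0.89, and 0 of 10000 random lists matched on mean expression had a median as low. Among them Iigp1 was at -2.10 ± 0.45 and Gbp7 at -1.37 ± 0.37. The random lists were drawn gene by gene, while members of a family may vary together, so their count may overstate the evidence. That the family as a whole is lower in the ileum stays a hypothesis, found and tested on the same arrays. In the colon the median of the 11 genes was 0.05, with 0 past the threshold.

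In the gasdermin C family, whose members form membrane pores, Gsdmc (-1.26 ± 0.21), Gsdmc4 (-1.08 ± 0.19), Gsdmc3 (-1.05 ± 0.20) and Gsdmc2 (-0.84 ± 0.17) passed over all genes in the ileum. The other 2 genes, Gsdmcl1 at -0.18 and Gsdmcl2 at 0.01, had a median of -0.0850, and 2 genes are too few to test whether the family as a whole is lower. In the colon the median of the 6 genes was 0.23, with 0 past the threshold. Probes shared between these related genes were not tested for.

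The changes of 17 clock genes in colon and ileum went together across genes, with Pearson's r of 0.862 and Spearman's rho of 0.801, and r of 0.745 without the 2 genes farthest from the median. Of 10000 random lists of the same size 0.11% gave an r as high, but such lists hold unrelated genes. Genes of the clock move together and are not independent replicates. Deviations of same-numbered vancomycin arrays of the 2 tissues correlated at 0.107 to 0.236, so r need not be 0 without an effect of vancomycin. A shift of the clock shared by both tissues, such as a difference in the hour of collection between the treatment groups, may account for the agreement, as a hypothesis. The labels give no hour.

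Across all genes the changes in colon and ileum had Pearson's r of 0.182, where genes are not independent replicates. Of 100 drawn pairs of splits 8 gave an r as high, the highest other being 0.259, so a change shared by both tissues was left undecided.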
